A study of Caenorhabditis elegans with 2 samples.

How the data were processed

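Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on eGFP-tagged SEM-4 in whole Caenorhabditis elegans at the L2 larval stage. SEM-4 is a zinc-finger transcription factor of the Spalt family. Per the labels, the animals were of mixed sex and of strain OP57, which carries an integrated tagged sem-4 transgene in an unc-119 background, and the libraries had a size range of 150 to 350. Both samples belong to 1 group and are labelled as biological replicates 1 and 2. The labels do not describe how the animals of each replicate were grown, so nothing printed here measures variation between separate populations beyond these 2 samples.

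The values used were peak lists made by the authors. Per the deposited text file lists, relaxed peaks were called for each replicate alone and on the pooled alignments of both replicates, each with a control, and a thresholded list was then derived from the pooled and replicate lists by the irreproducible discovery rate (IDR). Column 7 of each deposited list was read as a signal value per peak and column 9 as the −log10 of a q-value, following the narrowPeak layout named in the deposited text file lists. The aligner, the peak caller, the IDR threshold and all versions were not given in the sources used here. The signal and −log10 q values are the authors' own for each peak. Their scale is set by the reads of each list, so signal was used only to describe, rank or select peaks within a list. The lists give no read counts, so the depth of each replicate is unknown and no counting error could be attached to a peak. The control library was not analysed here, and the text file lists were read only for how the lists were made.

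The thresholded list on assembly ce11 is called the reproducible list below. It held 2490 peaks, and these were exactly the 2490 peaks of highest signal in the pooled relaxed list of 30000 peaks. Membership thus followed pooled signal, and the name does not mean that each peak ranked high in both replicates. The other 27510 pooled peaks served as background, because they could have passed the threshold and did not. Every ce11 peak lay within the chromosome lengths of the matching reference genome, WBcel235, and gene models came from Ensembl release 115. Lists on the older assembly ce10 were compared as counts and shares only, and no coordinate was converted. Coordinates are 1-based and on ce11.

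A peak was placed by its summit. Classes were assigned with the priority coding exon, 5' UTR, 3' UTR, exon of a gene that encodes no protein, intron and intergenic, and introns were those of protein-coding genes. The promoter window ran from 1000 bp upstream to 200 bp downstream of any annotated start of a protein-coding transcript. Peaks of different lists were matched when they shared at least 1 bp, and where several peaks matched, the one with the best rank in the replicate's list was taken. For named peaks, the replicate value is that of the overlapping peak with the nearest summit. Shares were compared with Fisher's exact test, two-sided, against the background peaks. Gene lists were compared in the same way over the 7675 protein-coding genes with a pooled relaxed summit in the window. P-values were adjusted by the Benjamini-Hochberg method over the 6 classes, the 6 chromosomes or the 25 gene lists, with a threshold of 0.05. They cover peaks or genes, which are not independent animals, and neighbouring genes can share a summit.

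Motifs were counted on both strands in 101 bp around each summit and in a pair of 51-bp flanks centred 200 bp away on either side. Peaks with a motif at the summit only and in the flanks only were compared by an exact McNemar test, two-sided. The fixed motifs were TTGTST (S is C or G), a site described for SEM-4, the AT-rich ATATT of vertebrate SALL4, GAGAGA, CACGTG and the GATA-type TGATAA. All 2080 6-mers, pooled with their reverse complements, were then tested. The pair of flanks offers slightly fewer positions than the summit window. In random sequence with no planted motif the ratio of summit-only to flank-only peaks for TTGTST was 1.08.

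The gene lists, motifs, windows, tests and the first set of alternatives were chosen before the data were examined. The genes named are those with the nearest transcript start to each of the 20 peaks of highest signal, with any other gene whose promoter window held the same summit. Up to 4 members of each list with the strongest reproducible summit in the window are also named, as are all SEM-4 genetic targets, HSN regulators, Y-to-PDA factors and Hox genes. Genes named outside that rule are said to be so. The alternatives were other overlap rules, list sizes, promoter windows, gene universes, motif windows and backgrounds, including 10000 circular shifts of the reproducible peaks along their chromosomes. The higher-signal 1245 peaks and the top 2490 peaks of each replicate alone were used as well.

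Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The tests were tried on simulated data. A list of 60 genes planted among the 7675 at an odds ratio of 4 was called in 97 of 100 runs, with 9 calls among 2400 unchanged lists. Most of the real lists had fewer genes than this among the 7675, so that rate does not hold for them. Simulated genes were also independent of their neighbours, unlike real ones. A motif planted at 10% of 2490 simulated summits was recovered as both planted 6-mers, and no 6-mer was called without planting. The simulated summits and flanks shared the same base composition, unlike the real ones. The simulation therefore does not measure calls that arise from a difference in GC content. A peak list sharing 61.0% of its peaks with a copy gave 62.1% by the overlap rule. The class of 300 summits matched a direct look-up for all of them.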

Results

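SEM-4 occupancy was measured by ChIP-seq against the eGFP-tagged protein in whole L2 larvae of C. elegans, with 2 biological replicates of 1 group. SEM-4 is known from genetics to act in touch receptor neurons, the egg-laying HSN motor neurons, the sex myoblast lineage and the rectal Y cell, which becomes the PDA neuron. The design holds no second condition. The questions addressed were therefore where the protein was detected, how far the replicates' lists coincided, and which genes and sequences lay at the summits. The depth of the libraries is unknown because the lists hold no read counts.

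The strongest signal in the ChIP-seq lists lay over egl-5, the posterior Hox gene of the Abdominal-B type. A single block of 2681 bp on chromosome III, from 7814321 to 7817001, covered nearly the whole gene (7814374 to 7817141, plus strand) and held 5 reproducible peaks. Its top summits had signal values of 1964 in the 3' UTR at 7816541 and 1366 at 7814752, the latter inside an intron of egl-5 where the small non-coding gene C08C3.10, named after its values were seen, is annotated. A pooled summit of 376 lay over a coding exon at 7816025, while neither replicate's own list held a coding exon summit in the block. Outside this block, the highest signal was 740, upstream of the ribosomal protein gene rpl-3, and the median of the 2490 reproducible peaks was 57.7 (quartiles 47.3 and 79.9). The widest reproducible peak elsewhere spanned 459 bp. The block was found in both replicates, with signal values of 1450 and 522 at the 3' UTR summit and 870 and 559 at the intron summit, in replicates 1 and 2. Cloned or amplified egl-5 DNA in both libraries is not excluded as its source, as described below. The block is therefore not established as SEM-4 occupancy.

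**Figure D1:**
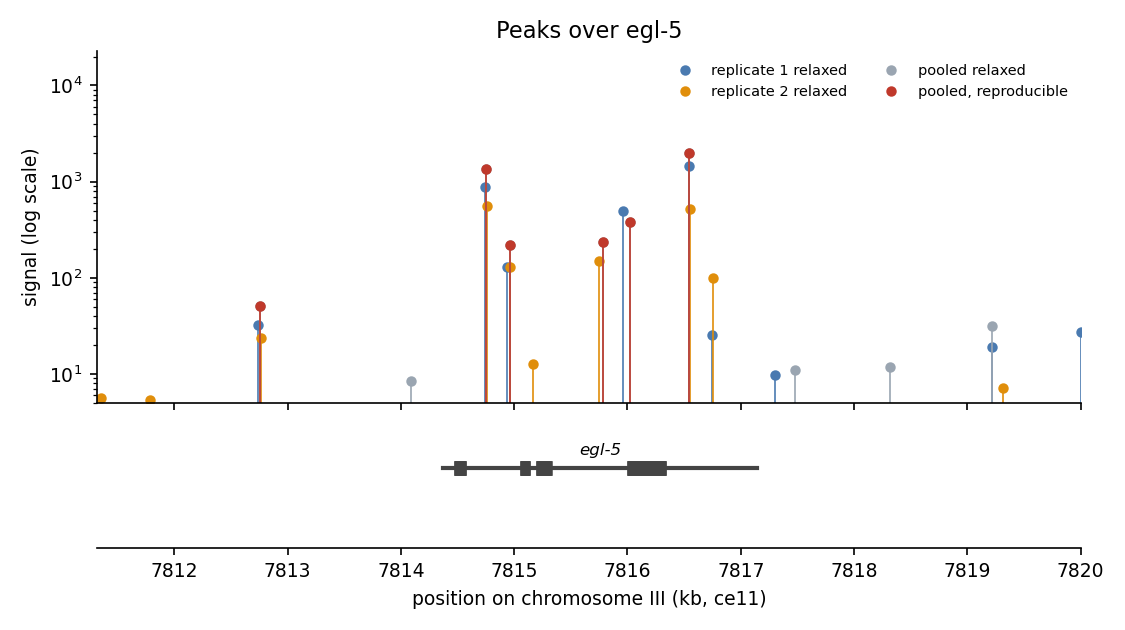
Peak summits over egl-5 on chromosome III, with position in kb on the horizontal axis and the authors' signal value on a log scale on the vertical axis. Points stand for summits in each relaxed list and, in red, for the reproducible list, and the lower track shows the gene with coding exons as thick bars. The highest pooled summits, at 1964 and 1366, stand near the 2 ends of the gene.

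Below egl-5, several of the highest peaks lay upstream of ribosomal protein genes. The summit upstream of rpl-3 (III, 3867586) was 268 bp from its start. It was followed by cox-5A, a subunit of cytochrome c oxidase, with a signal of 703 at 293 bp, and by an intron of Y111B2A.12 with 698. The AAA ATPase gene cdc-48.1 had 637 at 157 bp. Ribosomal protein genes filled the next places: rpl-15 had 554 (shared with K11H12.8), rpl-20 had 522 (shared with Y17G9B.5, the nearer start), rpl-35 had 407 and rps-1 had 385 (shared with ifet-1). Further down the 20 strongest were tasp-1 at 363 (shared with K01G5.10), the Pumilio-family gene puf-9 at 343, the histone gene his-37 at 336, serp-1.1 at 299 and the translation factor gene iff-2 at 295 (shared with F54C9.14). The remaining 4 summits of the 20 were distant from any start. A pair lay 7166 and 5862 bp upstream of F54F12.1 with signal values of 331 and 305. The others lay 8280 bp upstream of the AMPK subunit gene aakg-1 with 303 and 3966 bp downstream of the start of W02H3.3 with 295.

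The lists of top peaks of the 2 replicates were shared only in part. The rpl-3, cox-5A, cdc-48.1, rpl-15 and rpl-20 summits all ranked in the top 10 of both replicates. They were picked by signal pooled over both, so their high ranks in each partly follow from that choice. Of the 2490 reproducible peaks, 2483 (99.7%) overlapped a relaxed peak of replicate 1, 2482 (99.7%) one of replicate 2, and 2475 (99.4%) both. Of the other 27510 pooled peaks, 47.8% overlapped both. The reproducible list was derived from these lists by the IDR step and held the pooled peaks of highest signal. Its presence in both therefore partly follows from the selection and does not measure how well the replicates match. A high rank in each replicate was not required of each peak, since 46 peaks ranked beyond 10000 or were missing in at least 1 replicate. In the replicates' own rankings, 61.9% of the reproducible peaks lay within the top 2490 of both. When each replicate's top 2490 peaks were compared, 1574 of replicate 1 (63.2%, exact binomial 95% interval 61.3 to 65.1) were overlapped by those of replicate 2, and 1567 (62.9%) in the other direction. Random circular shifts of replicate 1's list gave a mean of 1.74%, and none of the 1000 shifts exceeded 2.93%. Across the 2475 reproducible peaks found in both, the Spearman rho of signal was 0.459 and the Pearson r of log2 signal was 0.59, and across the 15619 pooled relaxed peaks found in both the rho was 0.564, where peaks are not independent replicates. With at least 50% reciprocal overlap, the share of reproducible peaks found in both fell to 92.7%.

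**Figure D2:**
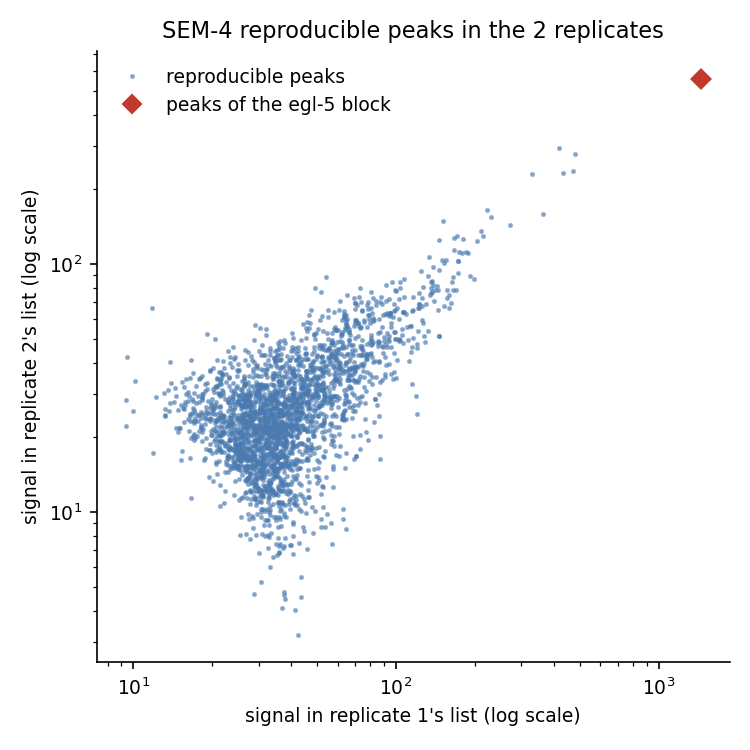
Signal of the reproducible peaks in replicate 1's list (horizontal axis) and in replicate 2's list (vertical axis), both on log scales, with 1 point per peak found in both lists and the best-ranked overlapping peak taken in each. The 5 peaks of the egl-5 block, drawn as diamonds, fall on 1 point because they share the same interval, and the Spearman rho across all points was 0.459.

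Reproducible SEM-4 summits lay between genes and close upstream of transcript starts. Intergenic sequence held 63.7% of them against 41.3% of the other pooled peaks (odds ratio 2.50). Exons of non-coding genes held 10.1% against 4.0% (odds ratio 2.70), and 5' UTRs held 3.01% against 2.11% (odds ratio 1.44). Coding exons held only 36 summits, or 1.45% against 12.1% (odds ratio 0.106), so that the pooled egl-5 exon summit, absent from each replicate's own list, belongs to a small class. Introns held 20.8% against 36.1% (odds ratio 0.466), and 3' UTRs held 0.884% against 4.37% (odds ratio 0.195). All 6 differences passed the threshold, with adjusted p-values from 3.56e-102 for intergenic sequence to 0.00511 for 5' UTRs by Fisher's exact test. The promoter window held 1376 summits, which is 55.3% against 30.8% of the other peaks and 26.1% of the genome (odds ratio 2.78, 95% interval 2.56 to 3.02, exact p = 2.16e-128). The median distance to the nearest protein-coding start was 607.5 bp against 1256 bp, and 76.8% of summits lay on its upstream side against 53.3%. More than 2000 bp from any such start lay 24.5% of the reproducible summits, against 33.5% of the other pooled peaks.

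**Figure D3:**
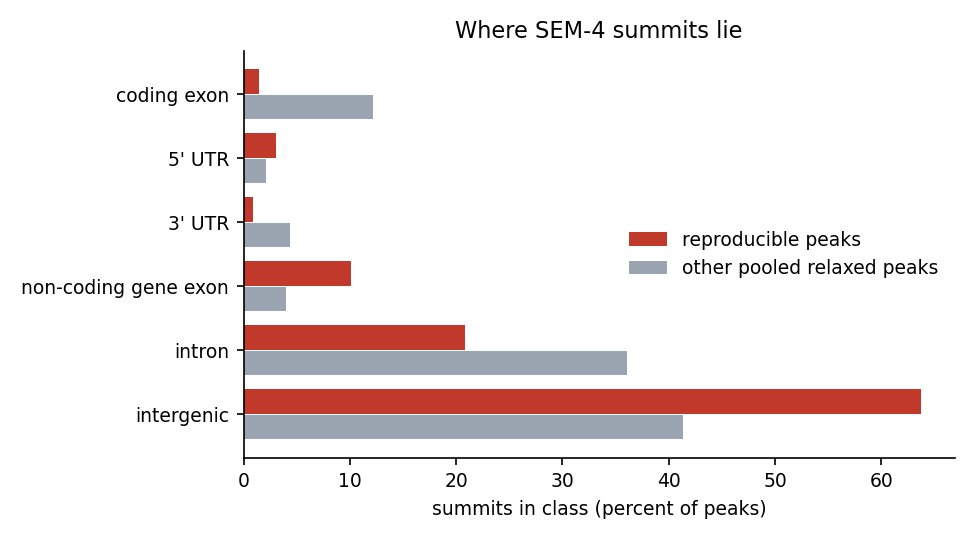
Share of summits in each annotation class (horizontal bars, percent of peaks from 0) for the 2490 reproducible peaks and the 27510 other pooled relaxed peaks. Intergenic sequence rises from 41.3% to 63.7%, while coding exons fall from 12.1% to 1.45%.

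Chromosome III, which carries egl-5 and the top peak of rpl-3, was the only chromosome to pass the test. It held 461 reproducible peaks, which is 18.5% against 16.3% of the other peaks (odds ratio 1.17, 95% interval 1.05 to 1.30, adjusted p = 0.0287, Fisher's exact test). Chromosome IV held 14.5% against 16.4% (adjusted p = 0.0513, Fisher's exact test). The X chromosome held 548 peaks, or 22% against 21.1%, with an odds ratio of 1.06 (0.954 to 1.17). The odds ratios of chromosomes I, II and V were 1.03, 0.921 and 0.953. The call for chromosome III was lost with the top peaks of replicate 1 alone, where the odds ratio was 1.11, and relative to chromosome length 4 chromosomes passed the test. Chromosome III and the X chromosome were higher, with shares of peaks 1.35 and 1.25 times their shares of the sequence, and IV (0.833) and V (0.710) were lower.

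Ribosomal protein genes were the list most often carrying a reproducible summit in the promoter window. Of 78 annotated members, 72 had a relaxed summit and 54 a reproducible one, against 1739 of all 7675 genes with a relaxed summit (odds ratio 10.5, 95% interval 6.06 to 19.1, adjusted p = 1.01e-19, Fisher's exact test). Their median best signal was 85.4, and rpl-3, rpl-15, rpl-20 and rpl-35 led with the values given above. Chemoreceptor genes, which encode the large families of sensory receptors, went the other way. Of their 1309 members only 83 had a relaxed summit and 6 a reproducible one (odds ratio 0.263, 0.0936 to 0.602, adjusted p = 0.00375, Fisher's exact test). The leading members were srh-16 with 94.4, sri-5 with 87.2, srh-2 with 56.2 and sre-23 with 49.7. The other 23 lists did not pass the adjusted threshold. The chemoreceptor odds ratio was 0.144 without replicate 1, 0.172 without replicate 2 and 0.0450 with all protein-coding genes as the universe. With a window of 500 bp upstream and 100 bp downstream, the chemoreceptor call was lost (odds ratio 0.237, adjusted p = 0.0847, Fisher's exact test), while its other alternatives gave adjusted p-values from 7.22e-43 to 0.0184 by exact or permutation tests.

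**Figure D4:**
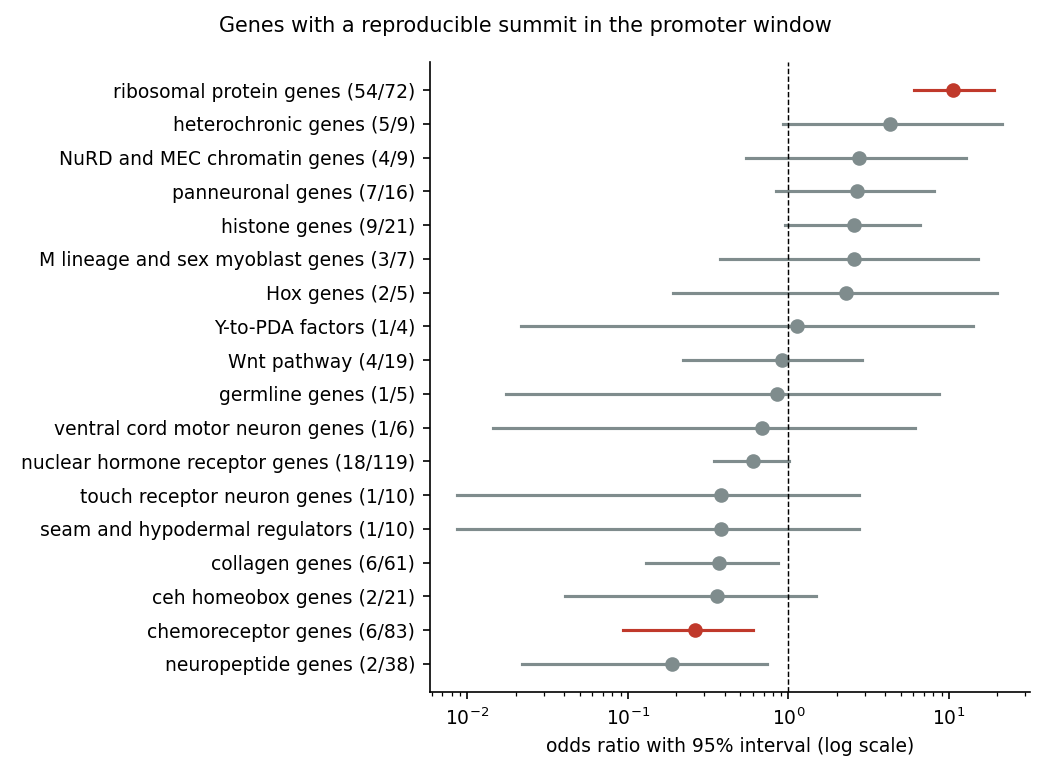
Odds ratio on a log scale, with 95% interval, that a gene of each list carries a reproducible summit in its promoter window, among protein-coding genes with a relaxed summit there. Numbers beside each list are members with a reproducible summit and members with a relaxed summit, lists with no reproducible member are not drawn, and the lists in red, ribosomal protein and chemoreceptor genes, passed the adjusted threshold.

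The genes that genetics has placed downstream of SEM-4 were too few for the test to decide whether they differ from other genes. Among the 8 SEM-4 genetic targets none had a reproducible summit in the promoter window, and 3 had a relaxed one (odds ratio 0, 95% interval 0 to 8.26). By nearest start the odds ratio was 1.98, without a call. The 3 were egl-5 with 8.53 at -288 bp from a start, the Hox gene lin-39 with 31.1 at -137 bp (pooled rank 3919), and the serotonin synthesis gene tph-1 with 9.78. The egl-5 block itself did not count there, since its nearest summit stood 372 bp downstream of the start, beyond the window. The touch neuron homeobox gene mec-3, the monoamine genes cat-1, cat-4 and bas-1 and the serotonin transporter gene mod-5 had no pooled relaxed summit in the window. Their nearest reproducible summits were 20095, 6476, 14256, 9216 and 80041 bp from a start. Of the 7 HSN regulators, egl-44 (40.0, rank 2539 in the pooled list, 1876 in replicate 1 and 20724 in replicate 2) and unc-86 (14.9) had relaxed summits, and sem-4, hlh-3, egl-46, ast-1 and egl-18 had none. The nearest reproducible summit to a start of ast-1 was 437 bp away, within the gene, with a signal of 42.2. Among the Y-to-PDA factors, egl-27 carried a reproducible summit (54.8) 222 bp upstream of a start, and 6 reproducible summits lay in its gene body, the best at 111. The factors ceh-6 (20.4) and sox-2 (15.6) had only relaxed ones. Among the Hox genes, mab-5 (60 at 837 bp upstream) and nob-1 (41.1 at 505 bp) were reproducible, while ceh-13 had 8.41 and php-3 had no relaxed summit in its window. The mab-5 summit ranked 667 in replicate 1 and 6023 in replicate 2.

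Regulators of developmental timing and neuronal genes held reproducible summits without passing the adjusted test. Of the 9 heterochronic genes, which time larval stages, 5 were reproducible (odds ratio 4.28, 95% interval 0.919 to 21.6, adjusted p = 0.149, Fisher's exact test). The RNA-binding protein gene lin-28 led with 114 at 47 bp upstream, then lin-14 with 56.2, lin-42 with 49.1 and lin-66 with 44.2. The lin-42 summit ranked 1236 in replicate 1 and 6934 in replicate 2. The body of lin-14 held 7 reproducible summits. Of 16 panneuronal genes 7 were reproducible (odds ratio 2.66, 0.841 to 8.04), led by the synaptic scaffold gene syd-2 with 111, the kinesin gene unc-104 with 60.2, rab-3 with 58.9 and egl-21 with 55.3. The rab-3 summit ranked 550 in replicate 1 and 4492 in replicate 2. Of 9 NuRD and MEC chromatin genes 4 were, namely lin-53 with 135, mep-1 with 78.0, egl-27 with 54.8 and lin-40 with 40.7. With all protein-coding genes as the universe, these 3 lists passed the adjusted threshold, with odds ratios of 13.1, 5.66 and 7.0, and the first 2 of them did so by nearest start as well, with 31.7 and 5.46. With the wider window only the heterochronic genes passed, with 6.48. All 3 passed with circular shifts, at 7.61, 8.67 and 10.03 times the shifted count. Such shifts do not keep peaks at promoters, and the share of summits in any promoter window was itself 2.16 times the shifted share. Among the higher-signal 1245 peaks none passed, and the odds ratio of the heterochronic genes turned to 0.792. Without replicate 1 and without replicate 2 the odds ratios were 2.25 and 4.69 for heterochronic genes, 1.57 and 2.19 for panneuronal genes and 9.40 and 1.60 for NuRD and MEC genes, and only the 9.40 passed.

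In the Wnt pathway 4 of 19 genes had a reproducible summit, and mig-5, a Dishevelled homologue, stood out with 255 at rank 32. It was followed by the beta-catenin gene wrm-1 with 77.9, lit-1 with 53 and lin-18 with 49.8. The lin-18 summit ranked 1862 in replicate 1 and 15841 in replicate 2. Of 21 histone genes 9 were reproducible (odds ratio 2.57, 0.954 to 6.65), led by his-37 with 336, his-67 and his-68 with a shared summit of 135, and his-31 with 79.1. Histone genes passed as higher without replicate 1 (3.46), without replicate 2 (4.89) and with circular shifts (5.0 times the shifted count). In the M lineage list 3 of 7 were, namely sma-9 with 63.1, mab-5 with the value given above and the FGF gene egl-17 with 44.2. Besides the Y-to-PDA factors, a single gene was reproducible in each of 4 lists. These were the alpha-tubulin gene mec-12 (52.4) of 10 touch receptor neuron genes, unc-37 (54.5) of 6 ventral cord motor neuron genes, the GATA factor gene elt-1 (72.3) of 10 seam and hypodermal regulators, and spo-11 (54.2) of 5 germline genes. Counts were low for neuropeptide genes, with 2 of 38 (ins-39 at 166 and nlp-20 at 73.1; odds ratio 0.189, adjusted p = 0.0514, Fisher's exact test). Collagen genes had 6 of 61 (odds ratio 0.370, adjusted p = 0.0851, Fisher's exact test), led by col-38 with 77.4, col-71 with 56.1 and col-3 and col-117 with a shared 52. Neuropeptide genes passed as lower with the wider window, all genes as the universe, nearest starts and without replicate 1. Collagen genes did so among the higher-signal 1245 peaks and without replicate 1, and stood at 1.31 times the shifted count with circular shifts, without a call. Nuclear hormone receptor genes had 18 of 119 (odds ratio 0.604, 0.343 to 1.01), but with circular shifts they passed as higher, at 2.23 times the shifted count. Under the same shifts, the share of summits in any promoter window was 2.16 times the shifted share. The 2.23 counts genes and the 2.16 counts summits, and a shifted count over all genes was not computed. The 2.23 is therefore not shown to set these genes apart from promoters at large. The leading nuclear hormone receptor genes were nhr-68 with 117, nhr-1 with 113, nhr-49 with 104.5 and nhr-47 with 97.7. The ceh homeobox genes had 2 of 21, ceh-38 with 144 and ceh-20 with 71. The ceh-20 summit ranked 524 in replicate 1 and 20347 in replicate 2. No reproducible summit was found for the 13 body wall muscle genes, 8 EGF-Ras and Notch genes, 2 intestine genes, 2 pharynx genes and 1 major sperm protein gene with a relaxed summit. In these lists 8 comparisons had an unadjusted p-value under 0.05 by Fisher's exact test.

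The sem-4 gene itself (I, 7038900 to 7048832, plus strand), the locus carried by the transgene, held no relaxed summit in any of the 3 lists, where mean density would give 2.97. Pooled relaxed summits were missing from 7036068 to 7056566, a distance of 20498 bp that was longer than 97.4% of gaps between summits. Gaps were ranked by number, and 780 were longer. A given gene lies in a long gap more readily than in a short one, so this percentile does not measure how unusual the locus is. Just upstream, the 20000 bp ending at 7036068 held 10 reproducible summits against a genome mean of 0.497 per window, with a best signal of 189 at 7028397 in ubql-1. The nearest reproducible summit to the start of sem-4 was 3039 bp upstream, with a signal of 45.4. The gene ubql-1, named here after its values were seen, held 3 of these 10 summits. A filter in the authors' processing that removed peaks over sem-4 is not excluded, so the missing summits do not show that the protein was absent there. Peaks in this region cannot be assigned to the native locus or to the transgene from these lists.

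**Figure D5:**
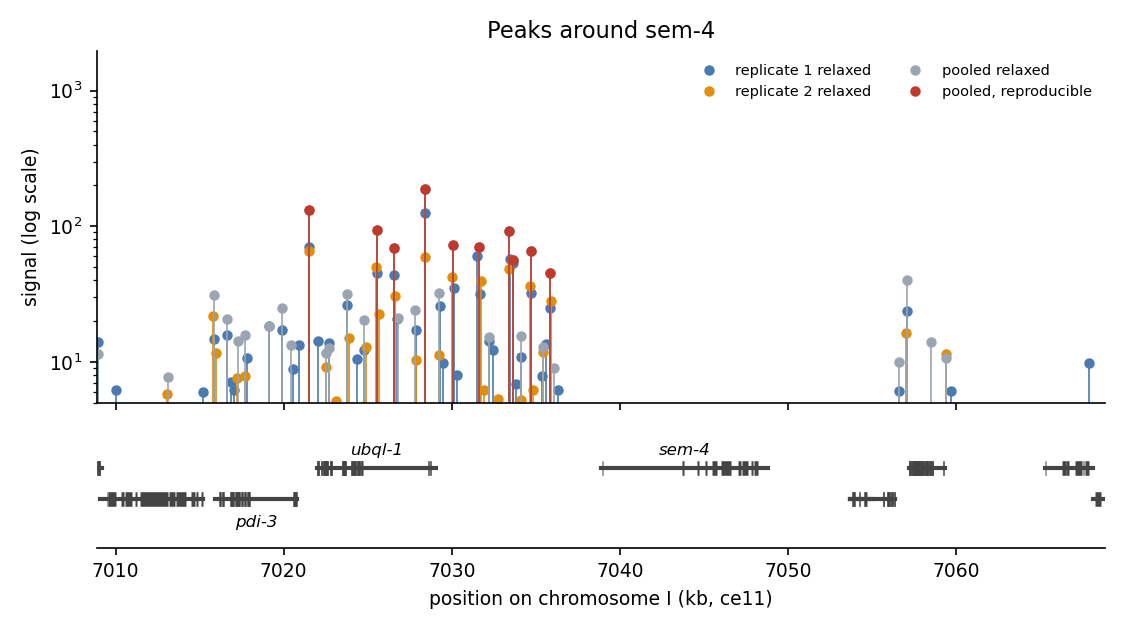
Peak summits around sem-4 on chromosome I, with position in kb on the horizontal axis and the authors' signal value on a log scale on the vertical axis, in the relaxed and reproducible lists, above a track of protein-coding genes. Summits crowd the 20000 bp upstream, where 10 are reproducible, and none falls within sem-4.

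Among the fixed motifs, GAGAGA marked SEM-4 summits more strongly than the site described for the protein. GAGAGA occurred within 50 bp of 30.8% of summits and in 10.6% of flanks, with 673 peaks carrying it at the summit only and 172 in the flanks only (ratio 3.91, 95% interval 3.30 to 4.65, adjusted p = 5.23e-70, exact McNemar test). TTGTST occurred at 18.6% of summits and 13.1% of flanks (ratio 1.53, 1.31 to 1.80, adjusted p = 9.50e-08, exact McNemar test). The E-box CACGTG occurred at 4.50% against 2.13% (ratio 2.20, 1.56 to 3.16). The AT-rich ATATT was less frequent at summits, at 13.4% against 32.6% (ratio 0.301, 0.256 to 0.352), and so was the GATA-type TGATAA, at 4.26% against 8.67% (ratio 0.447, 0.344 to 0.577). Among all 6-mers, 679 were more frequent at summits and 450 in flanks at the adjusted threshold of the exact McNemar test. Ranked by the p-value of that test, GAGAGA led the higher group. GACGCA (16.6% against 3.05%), ACGCAG (16.3% against 2.93%) and CGTCTC (19.3% against 4.86%) came from the same leading group. Several of that group had a higher ratio of summit-only to flank-only peaks than GAGAGA, such as GACGCA with 5.93, ACGCAG with 5.95 and AGCGCG with 7.59. GAGAGA, GAGACG (CGTCTC on the other strand), GACGCA and ACGCAG overlap in sequence. Whether they are parts of 1 longer site was not tested, so the counts do not establish a GA repeat as the site. By the same ranking, the lower group was led by AAAAAT, at 21% against 43.9%.

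Base composition moved with these motifs. Summit windows had a mean GC content of 46.3% ± 7.53 (SD, n = 2490 peaks), their flanks 36.5% ± 8.13 and the summits of the other 27510 peaks 35.9% ± 9.38. Against 2486 other pooled summits matched on GC content, GAGAGA was found at 30.8% of reproducible summits and 17.9% of the matched ones (odds ratio 2.05, 1.79 to 2.35, adjusted p = 7.97e-26, Fisher's exact test). For TTGTST the odds ratio was 1.22 (1.05 to 1.42, adjusted p = 0.0174), for CACGTG 1.42 (adjusted p = 0.0278) and for ATATT 0.812 (adjusted p = 0.0174), by the same exact test. TGATAA no longer passed, with an odds ratio of 0.770 (adjusted p = 0.0558, Fisher's exact test), against 3.45e-21 to 2.70e-04 under its other alternatives by the exact McNemar test.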

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

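Of 334 values recomputed under the alternatives, 287 kept their direction and call, stayed without a call, or stayed within the stated spread. Direction was not compared for values without a call in both settings, and some of these turned. The odds ratio of ventral cord motor neuron genes, for example, went from 0.683 to 3.75 without replicate 1. All 6 annotation classes, the promoter share and all fixed motifs except TGATAA kept their direction and call under every alternative run. Ranking by q-value gave a top-list overlap of 63.1%. The equal-position flanks were chosen after seeing the data. The reproducible list falls from 2490 to 1245 peaks by construction at the higher threshold. The share found in both replicates moved from 99.4% to 92.7% with 50% reciprocal overlap, to 92.4% with summits within 100 bp and to 99.8% in the higher-signal 1245. The overlap of top lists, 63.2%, was 66.8% for the top 500, 66% for the top 1000, 61% for the top 5000 and 58.4% with 50% reciprocal overlap. The odds ratio of chromosome III, 1.17, ranged from 1.11 to 1.20 without either replicate and lost its call at 1.11, without replicate 2. Chromosome IV passed the test at 0.808 in the higher-signal 1245, and against chromosome length IV (0.833), V (0.710) and X (1.25) passed. Higher gene lists numbered 2 with the wider window, 4 with all genes as the universe, 3 by nearest start, 6 with circular shifts and from 2 to 3 without either replicate, against 1. Lower lists numbered 0 with the narrower window, 2 with the wider window, 2 with all genes, 2 by nearest start, 2 in the higher-signal 1245 and from 1 to 3 without either replicate, against 1. Ribosomal protein genes were higher in every setting, from 6.01 by nearest start to 24.3 with all genes, against 10.5. Nuclear hormone receptor genes turned from an odds ratio under 1 to 2.23 times the shifted count. Summits in any promoter window stood at 2.16 times the shifted share, so calls against circular shifts include the general preference for promoters. The 2.23 counts genes and the 2.16 counts summits, so they are not directly comparable. With GC-matched summits TGATAA stood at 0.770 and missed the threshold. Apart from those built in by the construction of an alternative, the cause was not tested. No paired analysis was possible because the samples form 1 group. The unknown depth of each replicate limits what their ranks can show.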

Other observations

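The tests of cloned and of spliced egl-5 DNA, the tests of transgene copies near sem-4, the classes of non-coding genes and the genes named from them were chosen only after the results were seen, and the housekeeping lists after the strongest peaks were. Genes for snoRNAs carried SEM-4 summits more often than other genes that encode no protein. Among 26917 such genes, 9276 had a relaxed summit from 1000 bp upstream to 200 bp downstream of their start and 1095 a reproducible one (11.8%). For snoRNA genes the count was 92 of 219, or 42% (odds ratio 5.82, 4.36 to 7.73, adjusted p = 4.92e-30, Fisher's exact test). The piRNA genes, with 194 of 4324 (4.49%, odds ratio 0.211, 0.179 to 0.249), made up much of this background and lowered it. The shares of other classes were 21.8% of tRNA genes, 22.9% of miRNA genes, 25.9% of snRNA genes, 31.2% of 16 spliced leader RNA genes, 25.3% of lincRNA genes and 16.7% of genes annotated only as ncRNA. Pseudogenes had 7.02%. Among protein-coding genes with a relaxed summit in the same window the share was 22.7%, so most of these classes did not stand far from it, and that difference was not tested.

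The SL2 spliced leader genes sls-2.4, sls-2.1 and sls-2.8 had summits of 289, 277 and 274 at -23, -37 and -51 bp from their starts, at ranks 21, 26 and 27. Among snRNA genes, R07E5.16 had 177 at -28 bp and F38E11.11 had 136 at -68 bp. For miRNA genes, mir-54, mir-55 and mir-56 on the X chromosome shared a summit of 159. Many snoRNA genes lie within or beside protein-coding genes, and the strongest snoRNA summits, 637 for C06A1.9 and 554 for K11H12.12, are those named above for cdc-48.1 and rpl-15. How many summits of each class belong to a neighbouring protein-coding promoter was not tested.

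The egl-5 block stood apart in signal and width. Spliced egl-5 copies as the only source of the block are argued against, since each replicate had 2 intron summits of the block in its top 100. That rule was set after the summits were seen, and spliced copies beside another source are not excluded. Cloned or amplified genomic egl-5 DNA could give such a block, whose edges differed by at most 8 bp between the replicates. As first set, that test also counted a missing coding exon summit in the top 100 of either replicate against this explanation; neither replicate's own list held one, and the condition was removed after that was seen, because a genomic copy need not have its highest point on a small exon. A cluster of TTGTST sites, with 6 in the block at the 84.6th percentile of random windows, and cloned DNA cannot be told apart here, as neither value lies where it would exclude its explanation and the control library was not analysed here.

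Near sem-4, the stretch without peaks over the gene had a masked share of 31.9%, at the 48.4th percentile, and a GC content of 34.7%, at the 36.4th. These values argue against an excess of masked repeats or low GC content across the stretch as a whole. They are averages and do not measure how well reads map, so local effects within the stretch are not excluded. For the crowded summits upstream, extra copies of the transgene and SEM-4 binding to that region cannot be told apart. The lower of the replicates' percentiles of relaxed summits there was 99.9, but the window was chosen because summits crowded it, so this count restates the pattern. For the stretch over the gene, copies of the transgene in the control and a filter in the authors' processing stay open and were not tested. Whether the stretch needs a particular cause at all was not tested either. Its length, at the 97.4th percentile of gaps, does not decide on copies in the immunoprecipitated DNA alone, because it is the pattern itself and a filter could have removed peaks there.

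For the ribosomal protein promoters, a candidate explanation is general occupancy of highly used promoters. Proteasome, mitochondrial ribosomal protein, vacuolar ATPase and translation factor genes, without genes nearest to the 20 strongest summits, together had 44 of 126 members with a reproducible summit (odds ratio 1.85, 1.25 to 2.72, Fisher's exact p = 0.0017). This lies below the odds ratio of the ribosomal protein genes, 10.5 (6.06 to 19.1). No expression values were used, and these lists were not matched to ribosomal protein genes in how much they are used. The difference therefore does not show how much of the pattern general occupancy could account for. No single list of these 4 passed on its own, the lowest adjusted p being 0.080 for translation factors (13 of 32, Fisher's exact test). TTGTST occurred at 18.9% of the 53 summits in ribosomal protein windows and 18.1% of the 1323 in other promoter windows (odds ratio 1.05, 0.466 to 2.17), an interval too wide to decide whether such sites contribute. GAGAGA was rarer at ribosomal protein summits, at 11.3% against 27.9% (odds ratio 0.330, 0.114 to 0.783, adjusted p = 0.0345, Fisher's exact test). With 53 summits in these windows and 766 reproducible summits carrying GAGAGA, the enrichment across all summits could not have rested on them whatever this test gave.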
